A study of Mus musculus with 2 samples.

How the data were processed

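H3K27me3 was measured by ChIP-seq in stomach from mouse embryos (strain B6NCrl) of 16.5 days, with tissue pooled from male and female embryos. There were 2 samples, both biological replicates of 1 group. Replicate 1 comprised 2 technical replicates and replicate 2 comprised 1. All 4 deposited peak lists were used, in the mm10 assembly. Per the labels, each replicate's peaks were called by the authors from its filtered alignments together with further source files whose role is not stated. The pooled list was derived from both replicates' alignments, and the replicated list from the pooled list and both replicates' lists. The aligner, the peak caller, its thresholds and the rule for the replicated list are not given in the sources used here. In the deposited lists each peak carries a signal value, read as the ratio (fold) of enrichment on a linear scale, and what it is relative to is not stated. Each also carries a −log10 p and a −log10 q from the authors' peak caller, and no deposited peak had a −log10 p under 2. The values were not rescaled, and peak values were used only within a list or across overlapping pairs. No file gave read counts, so the depth is unknown and no counting interval was computed.

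Gene positions were taken from GENCODE M21 on GRCm38.p6, with 21728 protein-coding genes on chromosomes 1 to 19 and X. A gene was marked when a replicated peak overlapped its 5′ end ± 2 kb by at least 1 bp, and the replicates' own lists served as the check. Values are means and SDs over 2 replicates of the bp covered in this window of 4001 bp. Random placements (100) moved peaks within their chromosome, outside runs of at least 100 unknown bases. The comparisons, the 25 gene lists and the pattern for olfactory receptor genes, the rule for named genes and most alternative settings were fixed before the data were examined. The lists covered Hox paralog groups, stomach and foregut regulators, gastric, squamous, intestinal, endocrine, smooth muscle, enteric, endothelial and mesothelial genes, regulators of other organs, signalling ligands, and imprinted, cell cycle, Polycomb and housekeeping genes. Of 437 fixed symbols 435 were found, and the noncoding H19 and Meg3 were not measured. By the rule, any list member could be named, as could the 25 protein-coding genes outside the lists with the most bp covered by replicated peaks within 10 kb and a peak in both replicates. The rule also took up to 5 list members marked in a single replicate, the 10 widest domains with their genes, and the replicated peak with the highest fold. Examples within a list were chosen among its members after their values were seen.

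Lists were compared with all other protein-coding genes by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 26 lists. As an alternative, 10000 random lists were matched on the observed over expected CpG ratio within 500 bp of the 5′ end. Domains joined replicated peaks across gaps of up to 3 kb. Alternative settings were windows of 1 and 5 kb, the pooled list, a −log10 q of at least 5, all transcript starts, other overlaps and gaps, CpG within 1 kb, and each replicate's list alone. Chosen after the data were seen were the starts of principal transcripts, replicated peaks overlapped by at least 50% of either peak in both replicates, and results without X. The procedure was tested on simulated peaks, where 100 of 100 gene starts with a planted peak were called marked and 3 of 200 random lists had a Fisher's exact p under 0.05. The planted peaks lay inside the window, so the first count checks only the code. The other peaks were placed singly and the lists drawn at random, so the second does not cover clustered peaks or neighbouring genes. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9. The samples form 1 group, so no test between groups was possible.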

Results

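H3K27me3, the trimethyl mark that Polycomb repressive complexes place on lysine 27 of histone H3 and that is associated with silenced developmental genes, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in the stomach of mouse embryos of strain B6NCrl at 16.5 days of gestation. Tissue was pooled from male and female embryos, and 41 embryos contributed to replicate 2. The series held 1 group of 2 biological replicates, so no condition, stage or tissue was contrasted with another, and the question addressed was where the mark lay in this tissue. Each replicate had its own deposited peak list, and a list called on the pooled reads and a list of replicated peaks drawn from it covered both. Replicate 1 had 46331 peaks covering 17.3 Mb and replicate 2 had 40395 peaks covering 15.1 Mb, a mean of 43363 ± 4197 peaks (SD, n = 2). The pooled list held 46519 peaks covering 23.6 Mb, and the replicated list held 17946 peaks covering 16.0 Mb. The lists carry no read counts, so the depth behind each peak is unknown.

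The mark lay over the starts of many developmental regulators of tissues other than the stomach, and over most of the stomach regulators examined. A gene was called marked when a replicated peak overlapped the 4001 bp centred on its 5′ end. By this definition 3013 of 21728 protein-coding genes were marked, or 13.9%. Of the 17946 replicated peaks, 32.1% lay within 2 kb of a gene's 5′ end, against a mean of 3.97% and at most 4.29% in 100 random placements of the same peaks within their chromosomes (permutation p = 0.0099, one-sided, the smallest that 100 placements can give). By the position of their midpoints, 28.5% of the replicated peaks lay within 2 kb of a gene start, against 3.26% of the placed peaks. Away from gene starts, 26.9% of all replicated peaks lay in introns, 7.09% in exons and 37.6% outside genes, against 35.1%, 3.21% and 58.4% of the placed peaks. The marked share of 26 gene lists, 25 of them lists of symbols and 1 a pattern for olfactory receptor genes, was then compared with that of all other protein-coding genes by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the 26 lists. The share was higher in 14 lists, lower in 2 and not past the threshold of 0.05 in 10. Genes are not independent replicates, so these p-values describe the libraries at hand, and each replicate's own list serves as the check.

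All 50 members of the list of central nervous system regulators, transcription factors that act in the brain, spinal cord and sense organs, had a replicated peak at the 5′ end, and all 50 were marked in each replicate's own list (Fisher's exact test, adjusted exact p = 1.15e-42, against 13.7% of the other genes). Peaks filled most of the 4001 bp window at Six3, a regulator of forebrain and eye (chromosome 17, 5′ end at 85613608), with 3755 ± 206 bp covered (SD, n = 2). Pou4f2, a factor of retinal ganglion cells, had 3850 ± 149 bp covered, and Neurog1, which commits cells to a neuronal fate, had 3650 ± 321 bp. The lowest coverage by replicated peaks in the list was at the pituitary and motor neuron factor Lhx3, with 1926 bp, or 1901 ± 36.8 bp over the replicates.

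**Figure D1:**
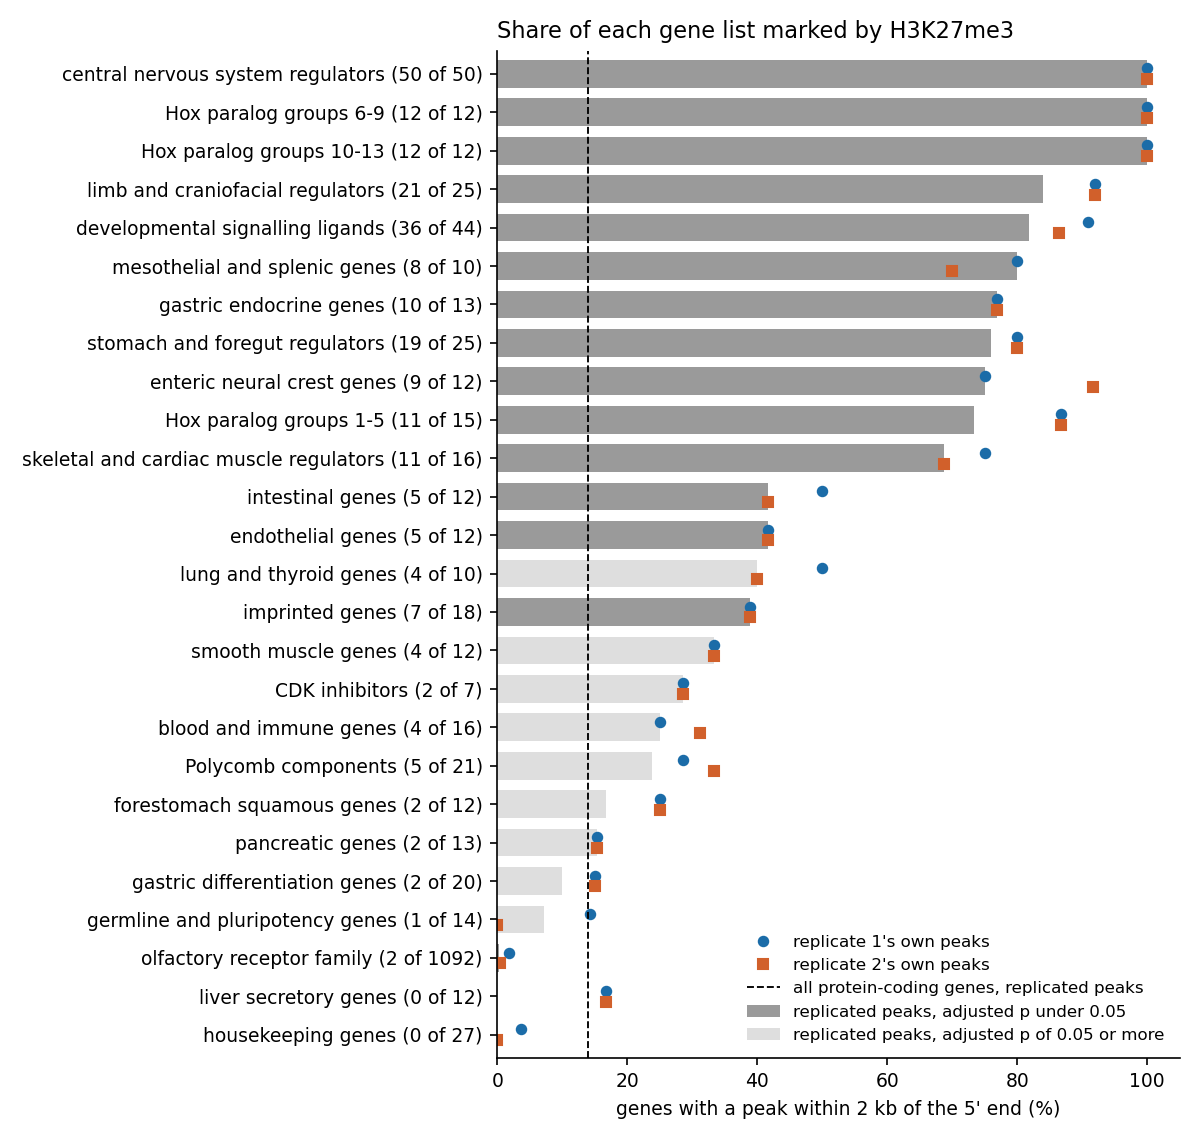
Share of each gene list with a peak within 2 kb of the 5′ end, in percent of the list's measured genes. Bars give the replicated peaks (dark where the adjusted p was under 0.05), circles replicate 1's own peaks, squares replicate 2's own peaks, and the dashed line the 13.9% of all protein-coding genes; central nervous system regulators and the later Hox groups stand at 100% in both replicates, and housekeeping genes at 0% by replicated peaks.

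Regulators of limb and face, regulators of skeletal and cardiac muscle and the secreted ligands of development were also marked more often than other genes. In the limb and craniofacial list 21 of 25 genes were marked (84.0%, adjusted exact p = 4.22e-14), with 23 marked in each replicate's own list. The homeobox gene Alx1 had 3492 ± 94.0 bp covered, Uncx, which patterns the vertebral column, had 3461 ± 151 bp, and Twist1, a factor of cranial mesenchyme, had 2474 ± 176 bp (SD, n = 2). Runx2 and Sox9, factors of bone and cartilage, had no replicated peak in the window, although Sox9 had 180 bp covered in replicate 2 alone. Among the signalling ligands 36 of 44 were marked (81.8%, adjusted exact p = 5.26e-23). Wnt7a and Wnt1 had 3789 ± 49.5 bp and 3596 ± 53.0 bp covered, Fgf8 had 3393 ± 779 bp and Ihh, the hedgehog ligand of cartilage and gut, had 3302 ± 612 bp. Bmp4 was covered over a shorter stretch, 1122 ± 6.36 bp, and Fgf10 and Bmp5 carried no peak in either replicate. Skeletal and cardiac muscle regulators were marked in 11 of 16 cases (68.8%, adjusted exact p = 2.07e-06), among them Irx4, a ventricular factor, with 3864 ± 110 bp and Myod1, the skeletal muscle determinant, with 3360 ± 503 bp.

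Genes that regulate the stomach and foregut themselves were also marked more often than other genes. Of the 25 stomach and foregut regulators 19 were marked (76.0%, against 13.8% of the other genes, Fisher's exact test, adjusted exact p = 1.88e-11), with 20 marked in each replicate's own list. They included Barx1, a factor of stomach mesenchyme (chromosome 13, 5′ end at 48662998), with 2135 ± 522 bp covered (SD, n = 2), and Nkx3-2, a factor of gut mesenchyme, with 1968 ± 46.7 bp. Foxf1, which acts in gut mesenchyme, had 2517 ± 849 bp covered. The endoderm and foregut factors Sox2 (chromosome 3, 5′ end at 34650405), Gata4 (chromosome 14, 5′ end at 63271692) and Hnf1b had 2085 ± 158, 1586 ± 32.5 and 1614 ± 697 bp covered. Elf3, Ehf, Klf4, Klf5, Hnf4a and Id2, of which all but Id2 are best known from epithelia, had no replicated peak in the window. Klf4 had 225 bp covered in replicate 2 alone and Klf5 had 190 bp in replicate 1 alone.

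Genes of the mature gastric epithelium did not pass the threshold in either direction. Of 20 gastric differentiation genes 2 were marked (10%, adjusted exact p = 1), Aqp5, a water channel, with 3895 ± 19.8 bp covered and the junction gene Vsig1 with 844 ± 601 bp (SD, n = 2). Of 12 forestomach squamous genes 2 were marked (16.7%, adjusted exact p = 0.736), the transcription factors Pitx1 with 995 ± 123 bp and Grhl3 with 194 ± 19.8 bp. Vsig1 and Grhl3 had no peak with a −log10 q of at least 5. The endocrine list differed, with 10 of 13 genes marked in each replicate and by replicated peaks (76.9%, adjusted exact p = 1.43e-06). Neurog3, the determinant of gut endocrine cells, had 3536 ± 84.1 bp covered and Insm1, an endocrine zinc finger factor, had 3303 ± 41.7 bp, whereas Gast and Ghrl, which encode the hormones gastrin and ghrelin, and the histamine enzyme gene Hdc carried no peak. The other members, which include the hormone gene Sst and the secretory granule gene Chga, were all marked. Of 12 intestinal genes 5 were marked (41.7%, adjusted exact p = 0.0301). They were the intestinal and pyloric regulators Cdx2 (3645 ± 114 bp), Pdx1 (3103 ± 507 bp), Cdx1 (2377 ± 177 bp) and Satb2 (2369 ± 281 bp) and the mucin gene Muc2 (236 ± 16.3 bp), which had no peak with a −log10 q of at least 5. The intestinal call did not hold with a window of 1 kb, with pooled peaks, with replicate 2's list alone or with the starts of principal transcripts (adjusted exact p = 0.0739, 0.112, 0.0601 and 0.105, in that order).

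Among the other cell types that a whole stomach holds, genes of the enteric neural crest and of mesothelium and spleen were marked more often than other genes. In the enteric neural crest list 9 of 12 genes were marked (75%, adjusted exact p = 6.55e-06), including Phox2b (2903 ± 426 bp), Sox10 (2807 ± 132 bp) and the receptor gene Ret (2923 ± 401 bp, SD, n = 2), while the endothelin receptor gene Ednrb had a peak in replicate 2 alone. In the mesothelial and splenic list 8 of 10 were marked (80.0%, adjusted exact p = 1.02e-05), with 2907 ± 547 bp covered at the mesothelial factor Wt1 and 3243 ± 265 bp at the spleen factor Tlx1, and Pbx1 and Upk3b unmarked. Of 12 smooth muscle genes 4 were marked (33.3%, adjusted exact p = 0.105), among them Des (1278 ± 9.90 bp) and Cnn1 (1406 ± 140 bp), and the contractile genes Acta2 and Myh11 had no replicated peak, although Myh11 had 400 bp covered by pooled peaks. The smooth muscle list passed the threshold with a −log10 q of at least 5 (adjusted exact p = 0.042). Of 12 endothelial genes 5 were marked (41.7%, adjusted exact p = 0.0301). The receptor gene Kdr had 1671 ± 189 bp covered and the transcription factor gene Sox18 had 3301 ± 182 bp, while the adhesion gene Pecam1 had no peak. The endothelial call did not hold with pooled peaks (adjusted exact p = 0.112), with either replicate's list alone (0.0601 and 0.0794) or with the starts of principal transcripts (0.105).

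The lists of blood and immune, pancreatic, liver, and lung and thyroid genes did not pass the threshold. Of 16 blood and immune genes 4 were marked (25%, adjusted exact p = 0.326), including the blood stem cell factors Gata2 (3368 ± 375 bp) and Tal1 (3002 ± 208 bp). Of 13 pancreatic genes 2 were marked (15.4%, adjusted exact p = 0.736), Ptf1a (3311 ± 67.9 bp) and Rbpjl (2519 ± 149 bp), which encode partners in the exocrine transcription factor complex. Of 10 lung and thyroid genes 4 were marked (40.0%, adjusted exact p = 0.0592), including Foxe1 (3233 ± 374 bp) and Nkx2-1 (3246 ± 95.5 bp, SD, n = 2). The lung and thyroid list passed the threshold with a window of 1 kb (adjusted exact p = 0.0433), with a −log10 q of at least 5 (0.0239), with replicate 1's list alone (0.0422) and with peaks overlapped in both replicates (0.039). None of 12 liver secretory genes had a replicated peak (adjusted exact p = 0.464), and 1 of 14 germline and pluripotency genes did, the pluripotency factor gene Pou5f1 (adjusted exact p = 0.736). No lower count than that of the liver list is possible, so with 12 genes the test could not have called it lower. Its result therefore does not show that liver genes were marked like other genes. Imprinted genes were marked in 7 of 18 cases (38.9%, adjusted exact p = 0.0153), with Kcnq1 at 2870 ± 103 bp, Dlk1 at 2177 ± 532 bp and Igf2 at 1687 ± 9.19 bp, and the imprinted inhibitor gene Cdkn1c had no peak. The imprinted call did not hold with pooled peaks (adjusted exact p = 0.112), with replicate 1's list alone (0.0572) or with the starts of principal transcripts (0.0551). Of 7 inhibitors of cyclin-dependent kinases 2 were marked (28.6%, adjusted exact p = 0.326), the neighbours Cdkn2a (2807 ± 248 bp) and Cdkn2b (1480 ± 679 bp). Of 21 genes for Polycomb components 5 were marked (23.8%, adjusted exact p = 0.273), including Pcgf5 (1748 ± 553 bp) and Cbx8 (1139 ± 334 bp).

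Olfactory receptor genes and housekeeping genes were marked less often than other genes. Of 1092 olfactory receptor genes 2 were marked (0.183%, Fisher's exact test, adjusted exact p = 1.49e-67), Olfr522 with 236 ± 334 bp covered and Olfr95 with 762 ± 60.1 bp (SD, n = 2). No replicated peak lay at the start of any of 27 housekeeping genes (adjusted exact p = 0.0423). That difference did not hold with a window of 1 kb (adjusted exact p = 0.0991), with pooled peaks (7.41% marked, 0.198), with a −log10 q of at least 5 (0.137), with replicate 1's list alone (0.0763), with peaks overlapped in both replicates (0.098) or with the starts of principal transcripts (0.0521). Of the list members marked in only 1 replicate's own list, the 5 with the most covered bp were Pou5f1 (863 bp), Hoxa4 (683 bp), Bmp2 (648 bp) and the liver lipoprotein gene Apob (361 bp), all in replicate 1, and Hoxb3 (393 bp) in replicate 2.

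Within the Hox clusters, whose genes pattern the body axis from front (low paralog numbers) to back, the mean covered length was highest at groups 10 to 13 in both replicates. All 12 genes of paralog groups 6 to 9 and all 12 of groups 10 to 13 were marked (adjusted exact p = 1.84e-10 for each), and 11 of 15 genes of groups 1 to 5 were (73.3%, adjusted exact p = 9.27e-07). The difference in marked share between the first groups and the 24 later genes, tested after the data were seen, had a two-sided Fisher's exact p of 0.0166. It did not hold with either replicate's list alone (13 of 15 marked in each, exact p = 0.142), with a window of 5 kb (0.142) or with pooled peaks (14 of 15, 0.385). The mean covered length in the 4001 bp window was 1486 ± 84.6 bp in groups 1 to 5, 2770 ± 31.3 bp in groups 6 to 9 and 3365 ± 179 bp in groups 10 to 13 (SD, n = 2). Hoxd12 and Hoxc13 had 3878 ± 28.3 bp and 3758 ± 100 bp covered, Hoxa5 had 1018 ± 217 bp and Hoxb4 had 239 ± 68.6 bp, none of it with a −log10 q of at least 5, while Hoxa1, Hoxa2, Hoxa4 and Hoxb3 had no replicated peak in the window. Of these, Hoxa1 was marked in both replicates' own lists, over 657 and 506 bp, and Hoxa2 in neither. Whole clusters differed as well. In mm10, Hoxd (chromosome 2, 74668310 to 74765142) was covered over 78.2 ± 3.48% and Hoxc (chromosome 15, 102921103 to 103036852) over 70.3 ± 5.03% of its length. Hoxa (chromosome 6, 52155590 to 52260880) was covered over 40.9 ± 5.52% and Hoxb (chromosome 11, 96194316 to 96368256) over 36.7 ± 2.01%. The length of Hoxb includes a sparsely covered stretch between Hoxb13 and Hoxb9. The clusters also hold different paralog groups, so these shares do not compare like genes. The annotated 5′ ends of Hoxa3 and Hoxc5 lie beside genes of later groups, and those of Hoxd3 and Hoxd4 (74711927 and 74711929) share nearly all of their window, so these genes' marks are not separate from their neighbours'. The start of the principal transcript moves the window of Hoxc5 and Hoxd4, which were marked there too, but leaves that of Hoxa3 almost in place.

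**Figure D2:**
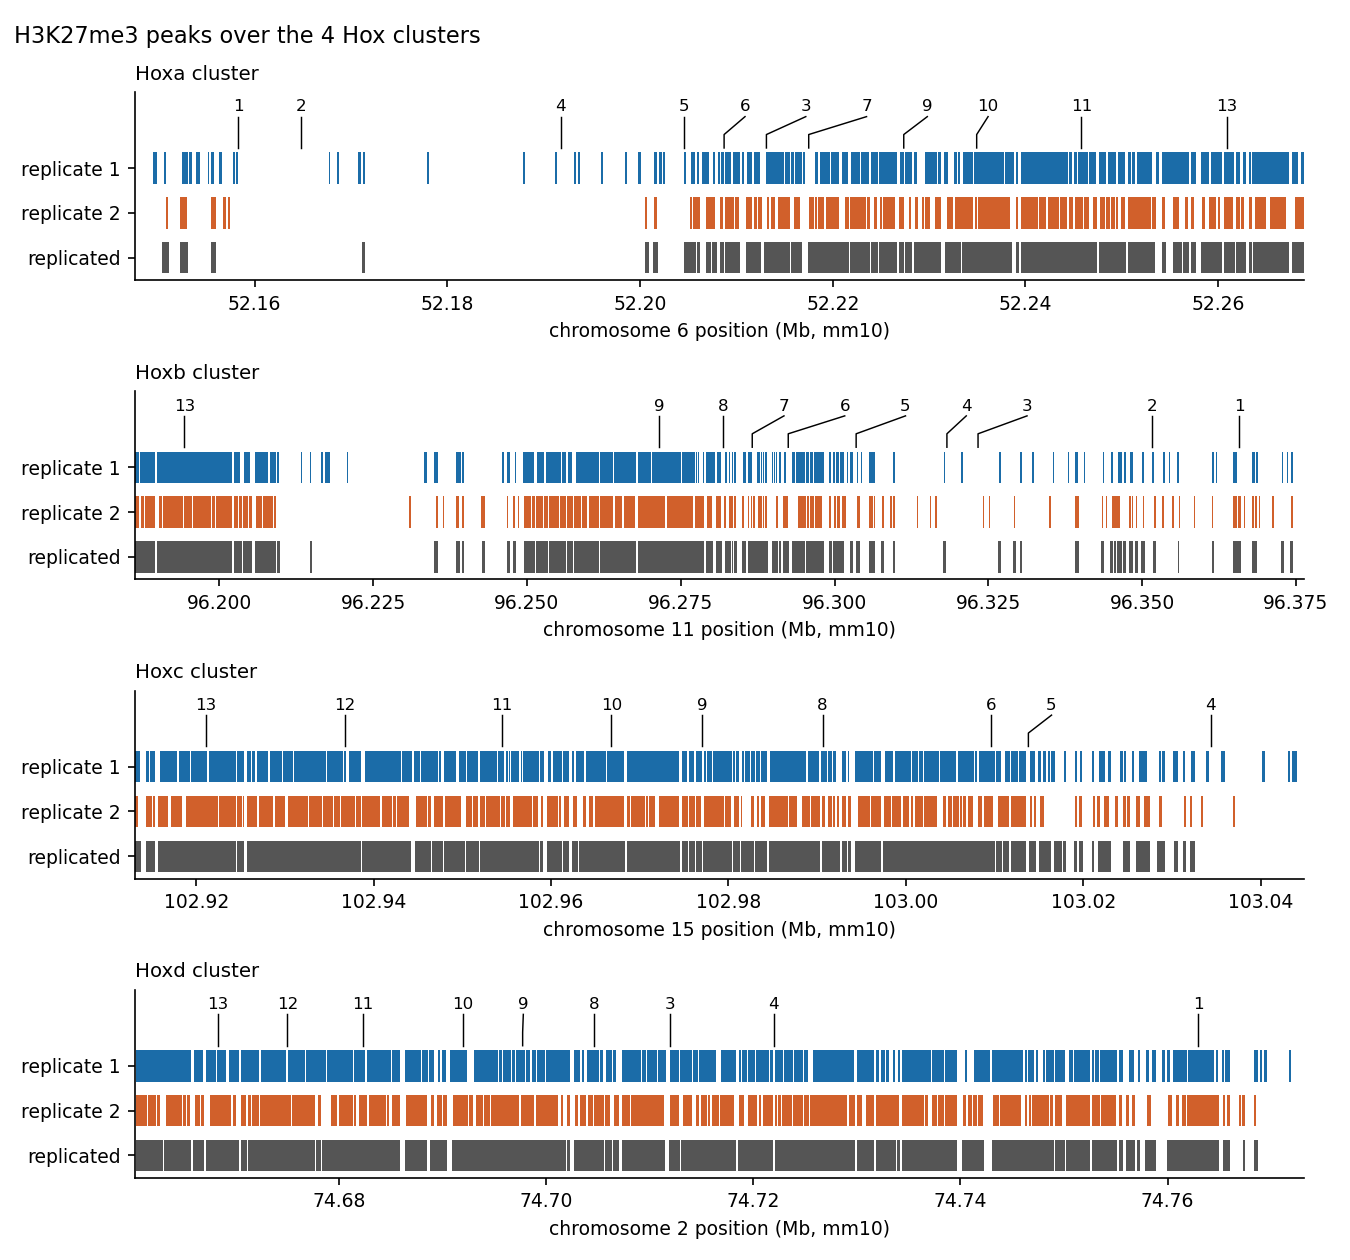
H3K27me3 peaks of replicate 1, replicate 2 and the replicated list over the 4 Hox clusters, by mm10 position in Mb, with the start of each gene's principal transcript ticked and labelled by paralog number. Peaks cover most of Hoxc and Hoxd and are sparse between Hoxa5 and Hoxa1, between Hoxb5 and Hoxb1 and over much of the stretch between Hoxb13 and Hoxb9.

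Outside the fixed lists, 25 genes were ranked highest by the bp covered within 10 kb of the 5′ end. Hmx1, a homeobox gene of sensory organs (chromosome 5, 5′ end at 35389108), came first with 19615 bp covered by replicated peaks and 18413 ± 223 bp over the replicates (SD, n = 2). Neurod2, a neuronal differentiation factor, followed with 17195 ± 193 bp, and Nr2e1, an orphan receptor of neural stem cells, had 15765 ± 817 bp, a value it shares with Ostm1, whose outermost annotated 5′ end is adjacent. The principal transcript of Ostm1 starts farther away, at 42678916, with 0 bp covered by replicated peaks within 2 kb. The remainder were Gm28230, Sim2, Hmx2, Sox1, Dmrt3, Vax2, Zic2, Crlf1, Nkx2-3, Lbx1, Grik3, 9230102O04Rik, Foxd2, Onecut2, Tfap2a, Ebf3, Prdm12, Evx2, Onecut1, Gm4881 and Dmbx1, with replicated coverage from 18906 bp down to 16570 bp. Nkx2-3, a factor of gut and spleen mesenchyme, was among them with 14300 ± 293 bp. Gm28230 (chromosome 2, 5′ end at 74726728) starts inside the Hoxd cluster and Evx2 beside it. Their coverage is therefore not separate from that of the Hoxd genes.

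Joined across gaps of up to 3 kb, the replicated peaks formed 7041 domains with a median width of 1.16 kb, of which 445 were 10 kb or wider. The 3 widest lay over Hox genes. The first, 134 kb over the Hoxc genes (chromosome 15, 102898543 to 103032548), was covered over 70.9 ± 6.24% by the replicates' own peaks (SD, n = 2). The second ran for 128 kb from Hoxa5 to Evx1 (chromosome 6, 52200501 to 52328758) and the third for 126 kb over Evx2 and the Hoxd genes (chromosome 2, 74642811 to 74768707). They were followed by a domain of 77.8 kb over the neural factors Zic4 and Zic1 (chromosome 9, 91344738 to 91422518). Next came a domain of 67.8 kb with no protein-coding gene, over the noncoding genes Mir9-3hg, Mir9-3 and Gm35040 (chromosome 7, 79493601 to 79561448), covered over 69.1 ± 1.21%. The other 5 lay over Hoxb5 to Hoxb9 (63.1 kb), Dmbx1 (56.6 kb), Pax3 (56.2 kb), Rhbg with Mir9-1 (53.5 kb) and Pax2 (50.2 kb). The replicated peak with the highest fold enrichment, 12.8 by the authors' value, lay within Rbfox3, which encodes the neuronal splicing factor NeuN (chromosome 11, 118567173 to 118573330), 93.4 kb from the nearest gene start. The peaks over that position had a fold of 11 ± 0.49 in the replicates' own lists (n = 2). Each replicate's own list gave more domains, 21659 in replicate 1 and 15391 in replicate 2, and peaks with a −log10 q of at least 5 gave 3865.

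Genes were marked most often where their starts had intermediate CpG content. The median ratio of observed to expected CpG within 500 bp of the 5′ end was 0.637 at marked genes and 0.518 at unmarked genes. When all genes were ranked by this ratio and divided into 10 equal parts, 1.29% of genes were marked in the lowest part, 27% in the fifth and 26.7% in the sixth, and 11.3% in the highest. The fifth part had 32.1 ± 1.69% and the highest 13.9 ± 1.63% marked in the replicates' own lists (SD, n = 2). Against 10000 random lists matched on this ratio, the share of stomach and foregut regulators marked, 76.0%, exceeded the matched mean of 17.3%, and the middle 95% of the matched lists ran from 4 to 32%. With such matched lists 15 lists were higher and 2 lower, and the lung and thyroid list was the one added (adjusted permutation p = 0.0253).

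**Figure D3:**
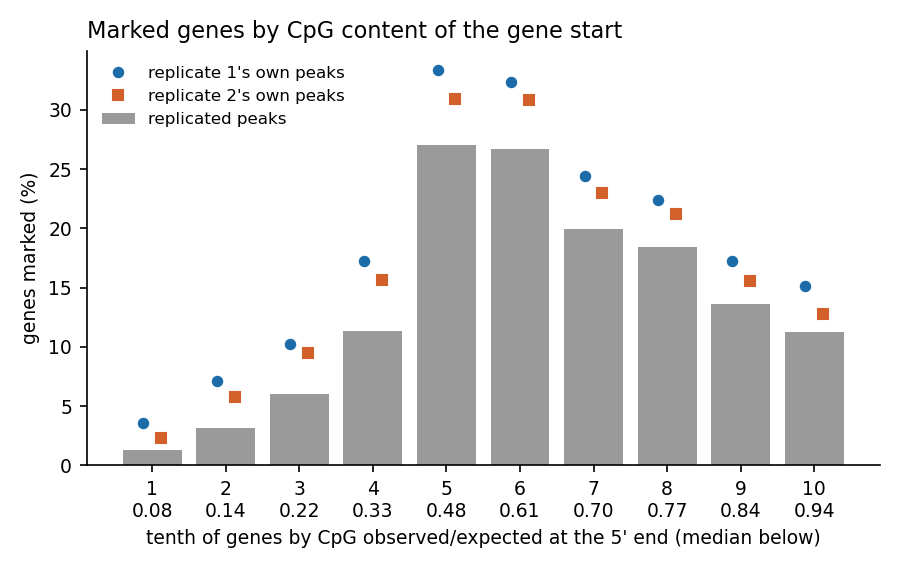
Share of genes marked, in percent, in 10 equal parts of all protein-coding genes ranked by observed over expected CpG within 500 bp of the 5′ end, with each part's median below its number. Bars give replicated peaks, circles replicate 1's and squares replicate 2's own peaks; the fifth and sixth parts stand highest, at 27% and 26.7% by replicated peaks.

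The X chromosome was the chromosome on which the replicates differed most. Replicate 1 had 3721 peaks on X, 8.03% of its peaks, covering 0.943 Mb with a median fold of 3.05, and replicate 2 had 8807, 21.8% of its peaks, covering 2.38 Mb with a median fold of 3.69. The median fold of autosomal peaks was 3.21 in replicate 1 and 3.69 in replicate 2. The covered length on X was therefore 2.53 times as long in replicate 2, while each of the 19 autosomes had less covered in replicate 2, at 0.682 to 0.838 times the length in replicate 1. Peaks per Mb on X were 1.23 times those of the median autosome in replicate 1 and 3.92 times in replicate 2. In the replicated list X had 14.0 peaks per Mb, the most of the 20 chromosomes by peak number and 2.10 times the median autosome, and 1.1 times with a −log10 q of at least 5. By covered length X had 6.61 kb per Mb in that list, less than chromosomes 2, 4, 5, 7, 9, 11, 15 and 19. With 2 replicates of 1 group no test of this difference was made. Marked genes numbered 2864 without X.

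**Figure D4:**
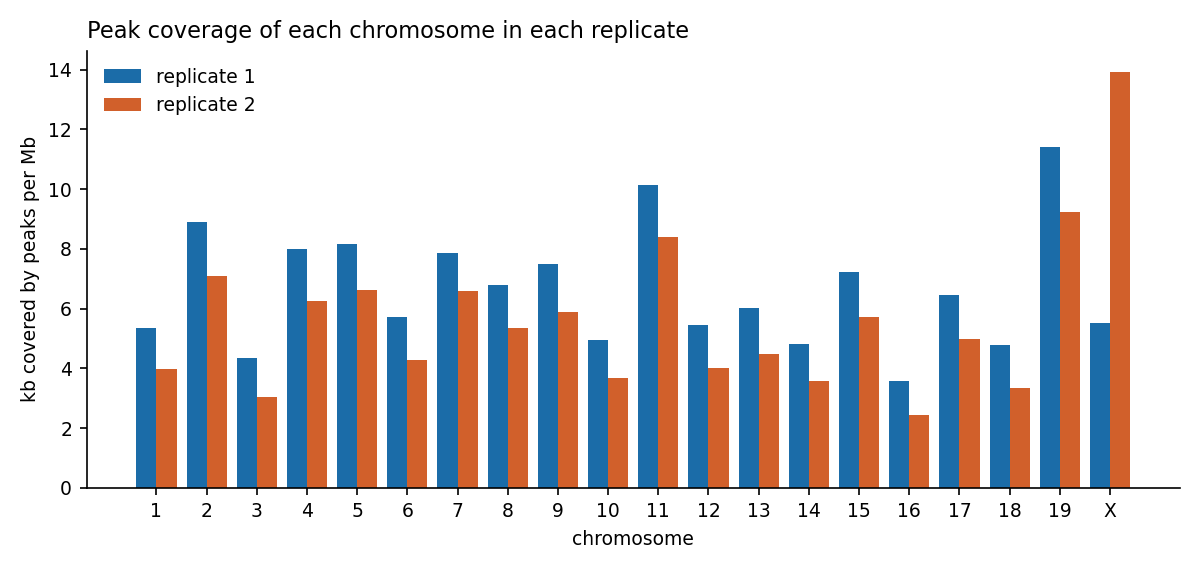
Length covered by peaks per Mb of each chromosome, in kb per Mb, for replicate 1 and replicate 2. Each autosome has less covered in replicate 2, and X has 2.53 times as much.

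The replicates shared far more peaks than chance placement gave, yet fewer than all. Of replicate 1's peaks 39.0% overlapped a peak of replicate 2 by at least 1 bp, and 46.2% of replicate 2's peaks overlapped replicate 1. For replicate 1's share, 100 random placements of replicate 2's peaks gave at most 1.39% (permutation p = 0.0099, one-sided, the smallest that 100 placements can give). Replicate 2's share was not compared with placements. Among peaks with a −log10 q of at least 5, the shares were 66.2% and 50.5%. Among peaks joined across gaps of up to 3 kb they were lower, 25.7% and 35.7%. On X alone 36.1% of replicate 1's and 15.3% of replicate 2's peaks were shared, and without X 39.3% and 54.8%. Over 18089 overlapping pairs the fold enrichments had a Spearman rho of 0.35 and a Pearson r of 0.38 on the log2 scale, across peaks, which are not independent replicates. The rho was 0.212 over the 2390 pairs with a −log10 q of at least 5. Of the pooled peaks 38.6% were kept in the replicated list, and 28.1% overlapped a peak of both replicates by at least 1 bp. In the replicated list 5312 peaks, 29.6%, did not reach an overlap of 50% of either peak in both replicates. Of these, 2873 overlapped no peak of replicate 1 and 2730 overlapped no peak of replicate 2. A replicated peak therefore need not have a peak in each replicate's own list. Many peaks were weak, with a q above 0.05 for 39.4% of replicate 1's, 30.6% of replicate 2's and 1.36% of the replicated peaks.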

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

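No paired analysis was possible because there is only one group of samples. The settings with peaks overlapped by at least 50% in both replicates, with the starts of principal transcripts and without X were chosen after the data were seen, as was the test between Hox groups with all of its settings. Across the settings run, 2220 to 4282 genes were marked and 21.7% to 46.7% of peaks lay near gene starts, above all placements in each setting. Between 11 and 16 lists were higher, and of the lists' results under these settings 237 kept their side of the threshold, 6 newly passed it, 17 no longer passed it and none reversed. The Hox test kept its side in 5 settings and lost it in 4. Replicates' X to median autosome peak density was 1.23 without replicate 2 and 3.92 without replicate 1.

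With a −log10 q of at least 5, the mean number of peaks per replicate was 4421, with 3608 in replicate 1 and 5234 in replicate 2. At that threshold the rho between folds was 0.212, 94.2% of pooled peaks were replicated, 57.8% of the Hox clusters was covered and there were 3865 domains. Joining peaks across 3 kb gave 18525 peaks per replicate, and an overlap of 1 bp in both replicates held for 28.1% of pooled peaks. With CpG counted within 1 kb, 68.4% of marked genes fell in the upper 5 of 10 CpG parts, against 64.9%. With pooled peaks this share was 60.4% and the Hox clusters were covered over 67.3%, against 63.4%. Leaving out each replicate gave 60.9% to 61.7% for CpG, 51% to 56.4% for the Hox clusters and 15391 to 21659 domains, from lists of single replicates that hold more and narrower peaks. The cause of the other shifts was not tested. With depth unknown, an absent peak does not show absence of the mark.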

Other observations

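The tests on microRNA genes, gene families (with the examples named), sequencing depth or threshold and the chromosome 17 repeat were chosen after the result was seen. Mir9-3 (3905 ± 7.78 bp covered within 2 kb, SD, n = 2) and Mir9-1 (3337 ± 118 bp) lay in 2 of the 10 widest domains. The remaining Mir9 gene and the Mir124 genes, which encode microRNAs of neurons, were then tested, and 4 of 4 were marked against 115 of 2189 other microRNA genes (5.25%, two-sided Fisher's exact p = 8.26e-06). Mir9-2 (chromosome 13, 83738814 to 83738885) had 1794 ± 196 bp covered, and Mir124a-1, Mir124a-2 and Mir124a-3 had 3030 ± 506, 2747 ± 281 and 3479 ± 411 bp.

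Families of genes that share the letters of their symbol were compared with all other genes where they had at least 15 members. The Hox and olfactory receptor families, tested above, were left out. Of 140 families 15 were marked more often, 8 less often and 117 did not pass the threshold (Fisher's exact test, Benjamini-Hochberg). Some of the 15 partly repeat the fixed lists, which hold all 19 Wnt, 10 of 22 Fgf, 7 of 19 Sox and 4 of 16 Pou genes. Synaptotagmin genes (Syt), for vesicle release, were marked in 11 of 17 cases (adjusted exact p = 4.61e-05), with 3266 ± 108 bp covered at Syt6. Inwardly rectifying potassium channel genes (Kcnj) were marked in 8 of 15 cases (adjusted exact p = 0.00409), with 3868 ± 50.9 bp at Kcnj12. Genes named Slc were marked in 83 of 371 cases (adjusted exact p = 0.000134). Most are solute carrier genes, but Slc4a1ap, Slc7a6os, Slc9a3r1 and Slc9a3r2 are not. Slc6a5 had 3935 ± 93.3 bp covered and Slc6a1 had 3648 ± 131 bp (SD, n = 2), while Slc6a9 and Slc6a13 had no peak in either replicate. Genes named Col, collagen genes apart from Col4a3bp, were marked in 20 of 45 cases (adjusted exact p = 2.18e-05), with 2835 ± 206 bp at the cartilage gene Col2a1. Among the marked Col genes, Col4a1 and Col4a2, Col4a3 and Col4a4, and Col4a5 and Col4a6 are pairs with neighbouring starts. Their windows overlap, so the marks within a pair are not separate, although the test counted each gene. Vomeronasal receptor genes (Vmn) were marked in 0 of 330 cases (adjusted exact p = 7.74e-20) and zinc finger genes named Zfp in 20 of 394 (adjusted exact p = 7.43e-07). These 6 calls held with each replicate's list alone. No lists matched on CpG content were drawn for the families. Of the other families counted above, the higher shares of Rgs and Mapk genes and the lower share of Rpl genes did not pass with replicate 1's list alone (adjusted exact p = 0.0862, 0.105 and 0.0602), nor did the lower share of Eif genes with replicate 2's (0.18).

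Replicate 2 had 2.38 Mb of the X chromosome covered and replicate 1 had 0.943 Mb. With a looser threshold in replicate 2, autosomes would also have gained covered length. All 19 autosomes had less in replicate 2, which argues against a looser threshold as the whole cause. Deeper sequencing was judged by the same count, but covered length includes weak peaks. Peaks with a −log10 q of at least 5, X included, numbered 5234 in replicate 2 and 3608 in replicate 1. The count of autosomes therefore does not decide on depth. For an even shift of the whole X, such as X copy number against a control, 48.6% of the X peaks found only in replicate 2 lay in gene bodies, above the 26% to 28.8% of 100 placements. X peaks found only in replicate 1 also did (46.7%, placements 25.2% to 29.9%), so the bound set beforehand does not separate a gain from other X peaks, and this explanation may hold. More female cells in replicate 2, with an inactive X that carries H3K27me3, could give the same. The 5 genes known to escape inactivation gained 1.51 ± 1.59 percentage points of coverage (SD over genes). The median of 10000 random sets of X genes was 1.13, and by the bound set beforehand a gain of at least that median counts against this explanation. However, the SD exceeded the gain, 62.7% of sets gained as little and 8.02% gained 0 or less. The test therefore had little power and decides nothing, and the last 2 explanations cannot be told apart.

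The pooled peak with the highest −log10 q, 118, lay on chromosome 17 (39843010 to 39846798) with a fold of only 2.83, at percentile 35.6 of the list. Of the 3 pooled peaks with the highest −log10 q, 2 lay over an annotated ribosomal RNA gene, where only 6 pooled peaks lay over any of 354 such genes. The second of these (39847866 to 39848914) had a −log10 q of 73.7 and a fold of 2.25. Copies of the ribosomal repeat collapsed in the assembly may therefore give these q values, while the median fold percentile of the 10 peaks with the highest −log10 q was 99.98. No biological explanation was tested.

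Stomach and foregut regulators were marked in 76% of cases in a tissue where several are known to act. CpG content of their starts does not account for the share, since the middle 95% of 10000 lists matched on it ran from 4 to 32%. A whole stomach mixes epithelium, mesenchyme, muscle, nerve and vessels, and the peak lists do not say in which cells a gene was marked, so a mixture of cells with and without the mark stays open. No biological explanation was tested.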
